A study of Mus musculus with 6 samples.

How the data were processed

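Gene expression was measured by bulk RNA sequencing in 6 mouse libraries on the C57BL/6 background: 3 labelled CML (chronic myeloid leukaemia) and 3 labelled WT (wild type). Per the labels, the source was untreated bone marrow cells, expanded ex vivo and sorted as lineage-negative, Sca1-positive, cKit-positive and CD150-positive. The labels give neither the order of sort and expansion nor the lineage antibodies. RNA was isolated with a column kit and libraries were made with a transposase-based kit, per the labels' protocols. Group and replicate number were read from the sample titles. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so every p-value measures the spread between these libraries, which may be technical.

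The authors deposited a table of estimated counts per gene, with 29872 gene symbols and 1 column per library. The values were not scaled to a common total, and between 34.0% and 36.1% of the entries of a library were not whole numbers, so they were read as estimated counts that need not be whole. STAR 2.7.3a, Partek 8.0 and the build mm10 are named in the submitters' processing notes, which give neither their roles nor their order. The gene annotation, the strand setting and the division of reads shared between genes are not given in the sources used here. Values of genes with near-identical copies, and of overlapping or antisense genes, are uncertain for that reason. Coordinates were taken from GENCODE release M21 on GRCm38 (the assembly of mm10) by exact symbol, which matched 28951 of the symbols (96.9%).

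Counts were rounded to whole numbers. Library totals ran from 13323552 to 17926866 counts, and 441 genes were at 0 in all 6 libraries. Genes with too few counts were removed with the filterByExpr function of edgeR (minimum count 10), which left 16221 genes for testing. These held at least 99.7% of the counts of each library. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust dispersion estimates and group as the only term. It was two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. CPM stands for the library-size-scaled counts that the cpm function of edgeR returns, with TMM scaling. Means are given with the standard deviation (SD) over n = 3 libraries per group. Genes at 0 in a whole group were given a lower bound on the fold, with 3 counts placed in each library of that group. Genes with 1 to 3 counts in a group have a ratio with an exact 95% binomial interval. The intervals were computed on counts summed over the libraries of a group, and the bounds on the group mean. Bounds and intervals therefore leave out the spread between libraries. Reads were amplified without molecular identifiers, so the intervals can also understate the counting error.

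A total of 37 gene lists (pathways, cell type markers, handling and label checks) were fixed before the data were examined, and 34 had at least 3 tested members. Members with too few counts were not tested. Those tested were 10 of 30 lymphoid, 12 of 18 dendritic, 15 of 26 erythroid and 16 of 22 monocyte genes. A gene near 0 in 1 group can pass the filter through the other group alone, and can then be called in only 1 direction. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 34 lists. Camera with an estimated correlation and fry were alternatives. The list of mitochondrially encoded genes had no member in the table and was not analysed here. The genes named in the text followed a rule fixed at the same time. It took the 10 largest changes in each direction among genes past the threshold, with no overlap between the groups and a mean of at least 5 CPM, leaving out unnamed gene models. It added Bcr, Abl1, Kit, Ly6a, Slamf1, Xist and the Y-linked genes. It then added, from each list, up to 4 called members with the lowest adjusted p, or, from a list without calls, at most the member with the lowest p. Any other gene is said to be chosen after its values were seen. Library totals and composition were compared with exact two-sided permutation tests over 8 measures, for which 3 libraries against 3 allow no p below 0.1.

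The pipeline was tested on simulated data drawn from the means, sizes and dispersions of these libraries (16221 genes, CML against WT, 3 libraries each). Of the genes changed by a factor of 1.5, 20.9% were recovered, of those changed by a factor of 2, 58.2%, and of those changed by a factor of 4, 92.4%. Of the 123 simulated calls, 7.3% were false. The simulation changed 67, 67 and 66 genes at these factors, against 2820 genes called in the data. The Benjamini-Hochberg cutoff depends on the share of changed genes, so the recovery rates need not hold for these data. The alternatives fixed before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, other count filters, thinning to the smallest library, a replicate block, a minimum log2 fold change of 1 and leaving out each library. After the data were seen, 3 more were added: a newer quasi-likelihood setting of edgeR, removal of 7 models of ribosomal, signal recognition particle and mitochondria-like RNA, and removal of GC content and length trends. Fits with a library left out or another count filter tested other sets of genes, so a list median there can cover other members than in the main test. Sequence identity of mitochondria-like models was measured with BLAST 2.17.0+.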

Results

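The data set holds 3 CML and 3 WT libraries of untreated, ex vivo expanded mouse bone marrow cells from a stem cell gate. The series set leukaemic cells beside normal murine stem and progenitor cells, and the labels of these libraries allow a single contrast, CML against WT. The CML libraries held 15430527, 13323552 and 15433562 counts for replicates 1, 2 and 3. The WT libraries held 17926866, 16619025 and 15930648 counts. Libraries of the same group correlated across genes with Spearman coefficients of 0.983 to 0.992, and libraries of different groups with 0.951 to 0.970. No pair differed by as little as sampling noise, since the smallest chi-square per degree of freedom between libraries was 8.62. By that measure CML replicate 1 and WT replicate 3 (30.9) had a value like CML replicates 1 and 3 (31.2) or WT replicates 1 and 3 (33.3). The measure includes a ribosomal RNA model with 1772 counts in CML replicate 1 and 198233 in CML replicate 3, which raises the value of that pair. By Spearman coefficient, CML replicate 1 was nearer to CML replicate 3 (0.986) than to WT replicate 3 (0.970). The first principal component, with 68.0% of the variance, separated CML from WT.

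**Figure D1:**
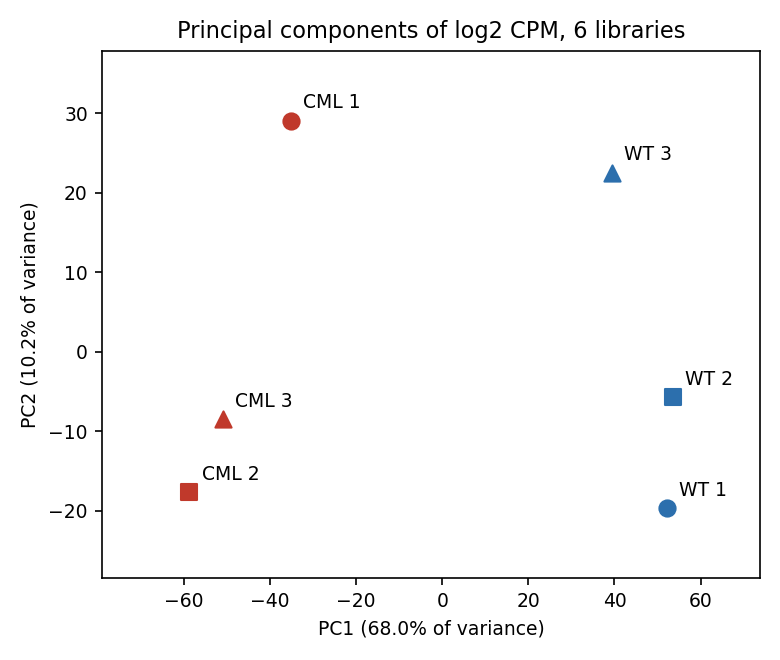
Position of the 6 libraries on the first (x axis, 68.0% of variance) and second (y axis, 10.2% of variance) principal components of log2 CPM, red for CML and blue for WT, with symbol shape for replicate number. All CML libraries lie below 0 and all WT libraries above 0 on the first component.

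The genes behind the gate were compared first. Kit, the receptor for stem cell factor, was at 309 ± 100 CPM in CML and 292 ± 9.05 CPM in WT (SD, n = 3), with a log2 fold change of 0.08 (SE 0.21, adjusted p = 0.842, edgeR). Without CML replicate 2 the value for Kit was -0.16. Ly6a, which encodes Sca1, was at 106 ± 57.5 CPM in CML and 52.2 ± 12.1 CPM in WT, a log2 fold change of 1.03 that did not pass (SE 0.42, adjusted p = 0.173; 0.49 without CML replicate 2). Slamf1, which encodes CD150, was lower in CML, at 14.2 ± 4.35 CPM against 24.7 ± 6.61 CPM (log2 fold change -0.80, SE 0.24, adjusted p = 0.0470). That call was lost without CML replicate 1 (adjusted p = 0.0946), CML replicate 3 (0.152), WT replicate 1 (0.134) or WT replicate 2 (0.158). It was also lost when scaled by library totals (0.0563), with a filter at a mean of 50 counts (0.0520), thinned to the smallest library (0.0593) or with GC and length trends removed (0.0700). As a list these 3 gate genes did not differ (camera adjusted p = 0.853; 0 members higher and 1 lower, also when adjusted over the list alone).

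Bcr and Abl1 are the mouse counterparts of the genes joined in the BCR-ABL fusion that drives CML. Neither passed the threshold: Bcr (chromosome 10, 75060592 to 75184921, GRCm38) was at 6.96 ± 1.53 CPM in CML and 7.49 ± 0.93 CPM in WT, and Abl1 (chromosome 2, 31688376 to 31804227) at 25.1 ± 1.76 and 20.6 ± 1.73 CPM. Their log2 fold changes were -0.11 (SE 0.21, adjusted p = 0.768) and 0.28 (SE 0.13, adjusted p = 0.167), and Bcr turned to 0.04 without CML replicate 1. Adjusted over the list alone, 0 of these 2 passed. Each CML value of Abl1 lay above each WT value, and groups without overlap were found for 35.01% of all tested genes. Human fusion sequence was not analysed here. Xist was abundant in every library, at 10809.7 ± 668 CPM in CML and 12166 ± 2721 CPM in WT, with a log2 fold change of -0.17 (SE 0.18, adjusted p = 0.551). The 4 Y-linked genes held between 3 and 9 counts in a whole library. Without WT replicate 3, Xist passed the threshold at -0.34 (adjusted p = 0.0359).

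Between the groups, 2820 of the 16221 tested genes changed (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 1652 were higher and 1168 lower in CML, and 958 and 222 of them changed by at least 1 on the log2 scale. The CML and WT values did not overlap for 2770 of the changed genes. Such separation held for 35.01% of all tested genes, where chance gives 10%. The higher share of the calls was 58.6%. Scaled by library totals alone it was 73.8%, with 2065 genes higher and 732 lower, and with the DESeq2 Wald test 52.3% (1619 and 1477). Without WT replicate 3 it was 49.0%, with 2021 genes higher and 2101 lower. The number of changed genes fell to 1861 without CML replicate 2, to 1771 without CML replicate 3, to 1857 without WT replicate 1 and to 1466 without WT replicate 2. Genes lower in CML numbered 675, 569, 688 and 455 in those fits. Genes higher in CML numbered 1011 without WT replicate 2.

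The largest increases were in genes almost silent in WT. Mcpt1, a mast cell protease gene (chromosome 14, 56017971 to 56020384), had 1600 counts over the CML libraries and 0 in WT, at least 188-fold higher. Its adjusted p was 0.0393, and it missed the threshold without CML replicate 2 (0.246), WT replicate 1 (0.125), WT replicate 2 (0.0809) or WT replicate 3 (0.0523), and with no low-count filter (0.115). Igfbp5, which encodes a binding protein of insulin-like growth factors (chromosome 1, 72857932 to 72874884), had 1017 counts in CML and 0 in WT, at least 120.9-fold higher (adjusted p = 6.72e-08). Tph1, the first enzyme of peripheral serotonin synthesis (chromosome 7, 46644641 to 46672537), was at 257 ± 142 CPM in CML and 0.23 ± 0.24 CPM in WT (log2 fold change 10.10, SE 0.87, adjusted p = 0.00222). Efna5, an ephrin ligand gene, had 683 counts against 1, a ratio of 728 with a 95% interval from 130.3 to 28800. Akr1c18, a steroid dehydrogenase gene, had 508 against 1 (ratio 542, interval 96.8 to 21430). Anpep, which encodes aminopeptidase N, had 1187 against 3 (ratio 422, interval 144 to 2049). Trgc4, a T cell receptor gamma constant segment, had 1033 against 3 (ratio 367, interval 125 to 1783), and Eomes, a T-box transcription factor gene, 931 against 3 (ratio 331, interval 113 to 1607). Mgl2, a lectin gene of macrophages, was at 27.2 ± 8.48 CPM against 0.08 ± 0.07 CPM. Sprr2a2 was at 70.3 ± 26.9 against 0.27 ± 0.25 CPM, a value that is uncertain because it has near-identical neighbours.

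The largest decreases were smaller. Nox1, a catalytic subunit of NADPH oxidase (chromosome X, 134086421 to 134221956), was at 0.70 ± 0.21 CPM in CML and 18.6 ± 1.69 CPM in WT, a log2 fold change of -4.71 (SE 0.24, adjusted p = 4.65e-08). Gem, which encodes a small GTPase, fell by 4.48 on the log2 scale from 128 ± 12.9 CPM in WT, and Tox, a transcription factor gene best known from T cells, fell by 4.39 from 23.1 ± 3.03 CPM. Hdac9, a histone deacetylase gene, fell by 3.26, and Mycn, a paralogue of Myc, fell by 3.03 (chromosome 12, 12936093 to 12941914). Cxcl10, an interferon-induced chemokine gene, fell by 2.76, and Slc6a15, an amino acid transporter gene, by 2.46. Clec4e, which encodes a pattern receptor of myeloid cells, fell by 2.46 from 547 ± 67.2 CPM in WT to 99.5 ± 9.58 CPM. Tmem47 and Adgrl4 had log2 fold changes of -2.62 and -2.42 (adjusted p = 0.0137 and 0.0157). Tmem47 missed the threshold without CML replicate 3 (0.0771), WT replicate 1 (0.0519) or WT replicate 2 (0.0621), and Adgrl4 without WT replicate 1 (0.0695); with no low-count filter both missed it (0.0662 and 0.0536).

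**Figure D2:**
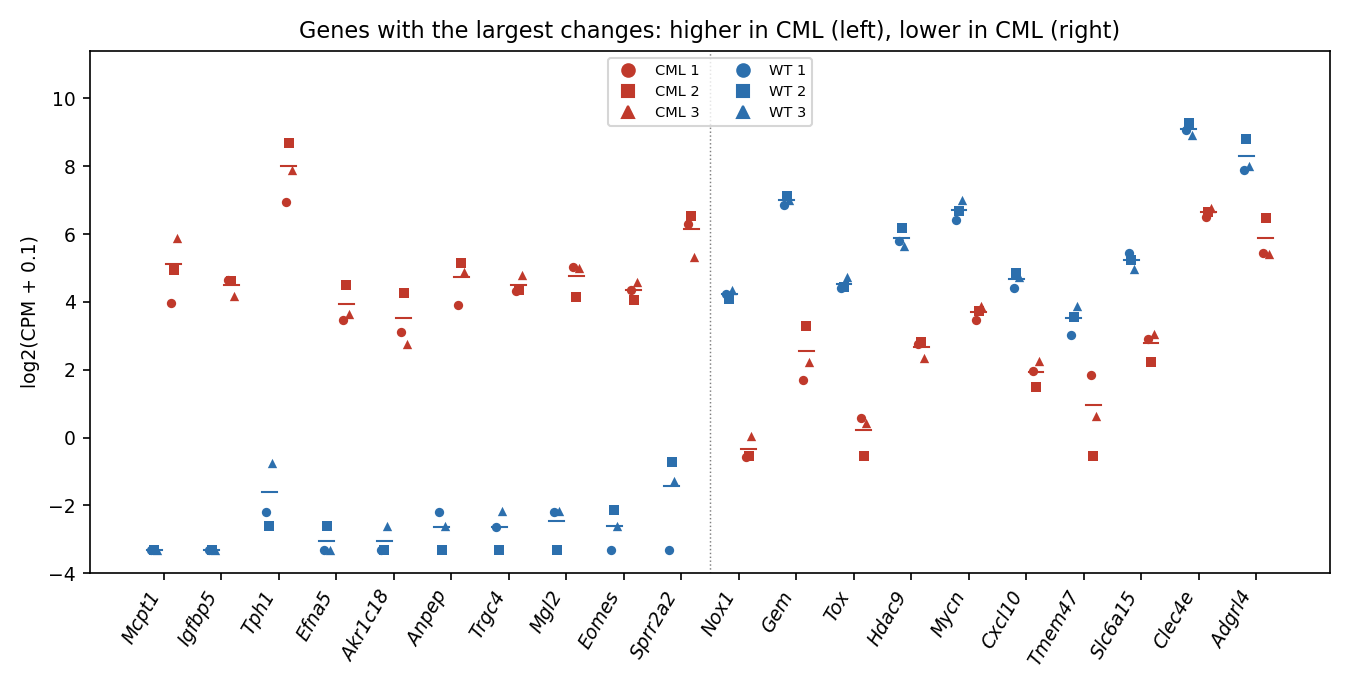
Expression of the 10 genes with the largest increases (left) and the 10 with the largest decreases (right) in CML, as log2(CPM + 0.1) on the y axis. Each point is a library (red CML, blue WT, shape for replicate), and lines mark the group means; Mcpt1 and Igfbp5 were at 0 in all WT libraries.

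Of the 34 lists tested, 17 differed at the preset correlation, 11 higher and 6 lower in CML. With a correlation estimated per list, camera called 0 of the 34 (4 at an unadjusted p under 0.05), while fry called 13. Those estimated-correlation p-values stand beside each of the 17 lists called at the preset correlation. In 4 of the 10 ways to split the 6 libraries into 3 and 3, the real one included, the preset test called at least 17 lists. The counts of the other splits ran from 5 to 24, so the preset test called lists in every split.

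Among the 34 tested lists, mast cell and basophil genes had the highest median log2 fold change. Of 24 tested members 14 were higher in CML and 0 lower (19 and 0 adjusted over the list alone), and 10 did not pass. The median log2 fold change was 2.91, the same with the 2 members at 0 in WT set at their bound (camera adjusted p = 1.77e-13; adjusted p = 0.480 with an estimated correlation). Hdc, the histamine-forming enzyme, was at 295 ± 99.98 CPM in CML and 5.01 ± 1.94 CPM in WT (log2 fold change 5.88, SE 0.42, adjusted p = 2.95e-04). Ccl9, a chemokine gene, reached 112 ± 33.6 CPM against 31.2 ± 3.03 CPM. The tryptase genes Tpsb2 and Tpsab1 had log2 fold changes of 6.40 and 4.14 (adjusted p = 0.00573 and 0.00217). Tpsb2 was at 177 ± 79.0 CPM in CML and 2.07 ± 1.63 CPM in WT. Tpsab1 was far scarcer, at 1.97 ± 1.14 against 0.10 ± 0.13 CPM, with 87 counts in CML and 5 in WT. How any reads shared between these tryptase genes were divided is not given, so the Tpsab1 value is uncertain. Tpsb2 missed the threshold without WT replicate 1 (0.0566). The list's median log2 ratio to the WT mean was 1.74 in CML replicate 1, 3.68 in replicate 2 and 2.80 in replicate 3.

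Monocyte and macrophage genes were also higher. Of 16 tested members 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 1.15 (camera adjusted p = 1.19e-08; adjusted p = 0.420 with an estimated correlation). Adgre1, which encodes F4/80, rose from 1.502 ± 0.06 CPM to 67.4 ± 15.2 CPM (log2 fold change 5.48, SE 0.21). Csf1r, the receptor for macrophage colony-stimulating factor, rose by 2.38, and Mrc1, the mannose receptor, by 4.47. Cd300a rose by 0.87 on the same scale. The per-library medians of this list were 0.78, 1.57 and 1.08 in CML replicates 1, 2 and 3. Neutrophil genes as a list did not differ (1 of 17 higher, 1 lower, the same adjusted over the list alone, camera adjusted p = 0.462). The list passed without WT replicate 3 (adjusted p = 0.0411). Itgam, an integrin gene of myeloid cells, rose by 2.03, and Padi4 fell by 1.66.

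MHC class II genes, which serve antigen presentation, were higher in 7 of 10 members and lower in 0 (8 and 0 adjusted over the list alone). Their median log2 fold change was 1.95 (camera adjusted p = 7.83e-05; adjusted p = 0.515 with an estimated correlation). Ciita, the master regulator of these genes, rose by 2.82 to 2.68 ± 0.41 CPM and H2-DMb2 by 1.49. H2-Ab1 and Cd74, the invariant chain, had log2 fold changes of 2.40 and 4.68 (adjusted p = 0.0145 and 0.0190). Cd74 missed the threshold without CML replicate 2 (0.0676), CML replicate 3 (0.0663), WT replicate 1 (0.110) or WT replicate 2 (0.0982). H2-Ab1 did so without WT replicate 1 (0.134), WT replicate 2 (0.0570) or WT replicate 3 (0.0614), and with no low-count filter (0.0694). The CML libraries were uneven: Cd74 stood at 40.9, 158 and 136 CPM in replicates 1, 2 and 3.

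Dendritic cell genes followed a like pattern, with 7 of 12 tested members higher and 0 lower (8 and 1 adjusted over the list alone) and a median of 2.28 (camera adjusted p = 4.58e-05; adjusted p = 0.515 with an estimated correlation; median 1.45 without CML replicate 3). Bcl11a, a transcription factor gene, rose by 1.24 to 249.99 ± 17.1 CPM, and Batf3, needed for a class of dendritic cells, by 3.74 to 1.20 ± 0.39 CPM. Irf4 and Fscn1, an actin-bundling gene of mature dendritic cells, had log2 fold changes of 3.95 and 5.93 (adjusted p = 0.00427 and 0.0245). Irf4 missed the threshold without WT replicate 1 (0.0635), and Fscn1 without CML replicate 2 (0.0783), WT replicate 1 (0.159), WT replicate 2 (0.126) or WT replicate 3 (0.0689), and with no low-count filter (0.0677). Fscn1 stood at 2.07, 15.6 and 17.7 CPM in CML replicates 1, 2 and 3.

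**Figure D3:**
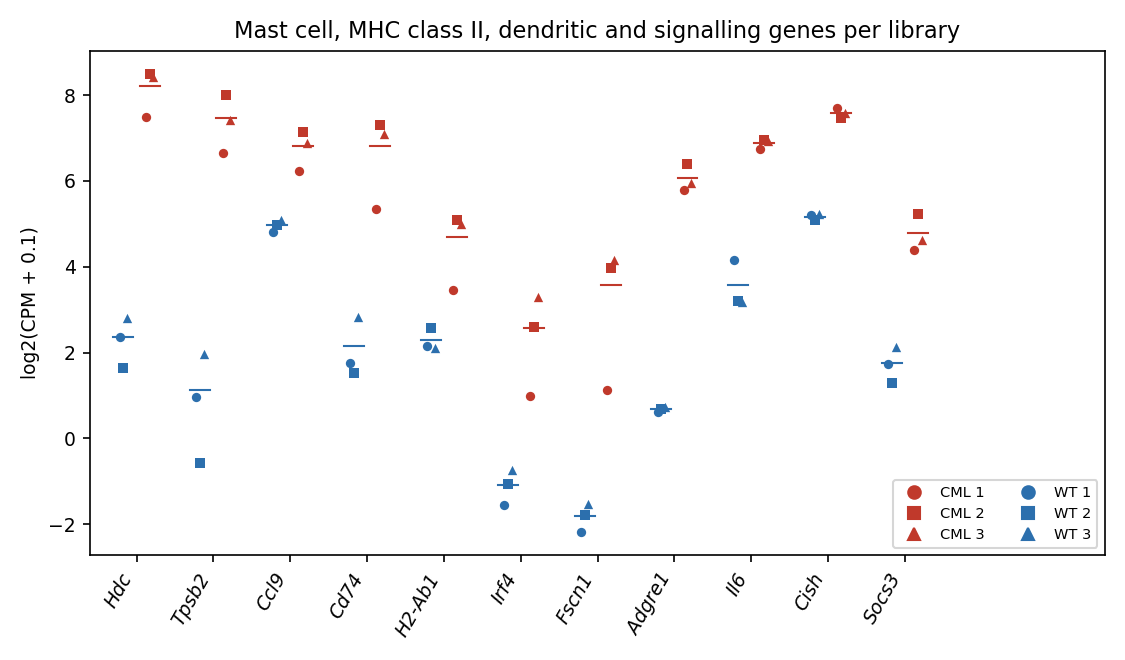
Expression per library of mast cell genes (Hdc, Tpsb2, Ccl9), MHC class II genes (Cd74, H2-Ab1), dendritic genes (Irf4, Fscn1), Adgre1, Il6, Cish and Socs3, as log2(CPM + 0.1) on the y axis. Points are libraries (red CML, blue WT, shape for replicate) and lines are group means. CML replicate 1 is the lowest CML library for Cd74 (40.9 CPM) and Fscn1 (2.07 CPM), and not for Cish.

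The lymphoid list was higher as well, and the erythroid list passed less firmly. Of the 30 lymphoid genes 10 had enough counts to be tested. Of these, 4 rose and 0 fell (6 and 0 adjusted over the list alone). The list median was 0.94 (camera adjusted p = 9.07e-04, or 0.515 with an estimated correlation). Tcf7 was at 0.27 ± 0.04 CPM in WT, and a gene that low in WT can hardly be called lower. The list's per-library medians were 0.40, 1.22 and 1.24 in CML replicates 1, 2 and 3. The members that rose were Cd79b (1.51), Tcf7 (3.71), Ighm (2.47) and Satb1 (0.96). Satb1 missed the threshold without CML replicate 2 (adjusted p = 0.109), CML replicate 3 (0.135), WT replicate 1 (0.224) or WT replicate 2 (0.156). It did so too with no low-count filter (0.0965), thinned (0.0579) or with GC and length trends removed (0.0839). In the erythroid list 5 of 15 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.57, camera adjusted p = 0.0320; adjusted p = 0.631 with an estimated correlation). Aqp1, a water channel gene, rose by 4.54 to 202 ± 47.0 CPM, and Klf1, an erythroid transcription factor gene, by 3.48 to 1.71 ± 1.17 CPM. Add2 rose by 3.36 to 1.35 ± 0.65 CPM. Tfrc, the transferrin receptor, fell by 0.92. The erythroid list missed the threshold without CML replicate 2 (adjusted p = 0.0899), with fry (0.0865), limma-voom (0.257), library totals (0.0523) or a filter at a mean of 50 counts (0.189, median 0.034). Its median was 2.18 without CML replicate 1, 1.69, 1.75 and 1.81 without WT replicates 1, 2 and 3, and 1.80 with no low-count filter. Those fits tested more genes (16696 without CML replicate 1 and 29299 with no low-count filter, against 16221). The medians of these fits can therefore cover other erythroid members, and their size is not the effect of the library left out. Per library, over the 15 members of the main test, the erythroid median was -0.10 in CML replicate 1, below each of the WT libraries (0.04, -0.07 and 0.13). It was 0.68 and 0.63 in CML replicates 2 and 3.

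STAT5 targets, genes that respond to a factor downstream of BCR-ABL and cytokine receptors, rose in 9 of 20 cases and fell in 4. Adjusted over the list alone the counts were 9 and 4. The list median was 0.39, or 0.255 with GC and length trends removed (camera adjusted p = 2.94e-04, or 0.420 with an estimated correlation). The list fixes no direction of response for its members, Bcl6 among them, so a rise of a member is not by itself a rise in STAT5 activity. The per-library medians of the STAT5 list were 0.23, 0.50 and 0.45 in CML replicates 1, 2 and 3. The mast cell, monocyte and NF-kB lists shared that order, lowest in replicate 1 and highest in replicate 2. Of the named STAT5 members Socs3 followed it, and Cish, Pim3 and Bcl6 did not. Cish, a feedback inhibitor of cytokine signalling (chromosome 9, 107296026 to 107302784), was at 192 ± 15.3 CPM in CML and 35.9 ± 1.86 CPM in WT (log2 fold change 2.42, SE 0.12). Socs3, of the same family, rose by 3.06 and the kinase gene Pim3 by 1.83. Bcl6, a transcriptional repressor gene, rose by 2.49 to 6.53 ± 1.18 CPM. Among reported surface and regulatory markers of CML stem cells, 7 of 19 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.00106; adjusted p = 0.515 with an estimated correlation). The fry test did not call that list (adjusted p = 0.0588), and its median was 0.50 without CML replicate 1, 0.046 without CML replicate 2 and 0.395 without WT replicate 3. Its median ratio to the WT mean was -0.06 in CML replicate 1, not above the WT libraries (0.06, -0.02 and 0.12), and 0.63 and 0.52 in CML replicates 2 and 3. Fcgr2b, an inhibitory Fc receptor gene, rose by 2.36 and Il1r1, an interleukin-1 receptor gene, by 1.48. Il1rap, the co-receptor of that family, fell by 0.86, from 53.3 ± 5.04 CPM in WT to 29.4 ± 5.17 CPM.

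RAS-ERK feedback and response genes moved in both directions, with 3 of 17 higher and 6 lower (3 and 8 adjusted over the list alone). As a list they did not pass (median -0.51, camera adjusted p = 0.0769). The list passed without CML replicate 2 (0.00238), CML replicate 3 (0.0371) or WT replicate 1 (0.0253), with no low-count filter (0.0304) and with GC and length trends removed (0.0165); its median was -0.254 without CML replicate 1. Spry2, an inhibitor of the pathway, fell by 1.48 and Etv4, a transcription factor gene induced by it, fell by 2.36. Egr1 and Ier3, immediate early genes, rose by 1.31 and 1.06.

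NF-kB and inflammatory cytokine genes were higher in 14 of 23 members and lower in 2 (15 and 2 adjusted over the list alone; median 0.89, camera adjusted p = 4.49e-08; adjusted p = 0.480 with an estimated correlation). Il6 was at 118 ± 8.42 CPM in CML and 11.9 ± 5.01 CPM in WT (log2 fold change 3.30, SE 0.25, adjusted p = 5.54e-05). Il1rn, the interleukin-1 receptor antagonist, rose by 3.07, and Birc3, an inhibitor of apoptosis, by 1.26, while Cxcl10 fell. The NF-kB list's per-library medians were 0.80, 1.05 and 0.99 in CML replicates 1, 2 and 3. Immediate early genes, fixed as a handling check because cell isolation induces them, rose in 7 of 16 cases and fell in 0 (7 and 0 adjusted over the list alone; median 0.45, or 0.295 without CML replicate 2 and 0.296 with no low-count filter; camera adjusted p = 2.94e-04; adjusted p = 0.515 with an estimated correlation). Junb rose by 1.41 and Btg2 by 1.37. Quiescence regulators, which share Btg2 and Egr1 with that list, rose in 9 of 23 cases and fell in 1 (10 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 7.83e-05; adjusted p = 0.480 with an estimated correlation). Per library the quiescence median was 0.17, 0.55 and 0.40 in CML replicates 1, 2 and 3. The mast cell, monocyte and NF-kB lists shared that order, lowest in replicate 1 and highest in replicate 2. Of the named quiescence members Egr1 followed it, and Cd82, Mxd4 and Btg2 did not. Cd82, a tetraspanin gene, rose by 2.63 to 396 ± 81.9 CPM, and Mxd4, a MYC antagonist gene, by 1.18.

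Genes of haematopoietic stem cell identity were divided. Of 32 tested members 5 were higher, 10 lower and 17 did not pass (7 and 11 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.00209; adjusted p = 0.420 with an estimated correlation). The list missed the threshold with limma-voom (0.0565). Its median was -0.245, -0.261 and -0.207 without CML replicate 2, CML replicate 3 and WT replicate 3, -0.277 with a filter at a mean of 50 counts and -0.030 scaled by library totals. Mmrn1, which encodes a platelet and endothelial protein, fell by 2.36. Runx1, a transcription factor gene of blood development, rose by 0.61, from 109 ± 6.42 CPM to 167 ± 6.40 CPM. The HOX list held 1 higher and 0 lower of 13 (0 and 0 adjusted over the list alone; camera adjusted p = 0.774). Hoxa10 had a log2 fold change of 1.73 (adjusted p = 0.0439). It missed the threshold without CML replicate 1 (0.0582), CML replicate 2 (0.128), WT replicate 1 (0.146), WT replicate 2 (0.167) or WT replicate 3 (0.135). It also did so with limma-voom (0.0638), no low-count filter (0.146), the newer quasi-likelihood setting (0.0515) or GC and length trends removed (0.0887).

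MYC targets and ribosome biogenesis genes fell in 15 of 30 cases and rose in 0 (15 and 0 adjusted over the list alone; median -0.39, camera adjusted p = 7.91e-07; adjusted p = 0.420 with an estimated correlation). Dkc1, a pseudouridine synthase gene, fell by 0.85, Npm1, which encodes nucleophosmin, by 0.75, Gnl3 by 0.68 and Srm, the spermidine synthase gene, by 0.62. Oxidative phosphorylation genes fell in 4 of 30 cases and rose in 0 (4 and 0 adjusted over the list alone; median -0.25, camera adjusted p = 8.71e-04; adjusted p = 0.515 with an estimated correlation), among them Ndufa4 with -0.60 (SE 0.12, adjusted p = 0.00426; -0.33 with GC and length trends removed). Mitosis genes fell in 4 of 28 cases and rose in 0 (4 and 0 adjusted over the list alone; median -0.22, camera adjusted p = 0.00298; adjusted p = 0.641 with an estimated correlation and 0.0869 with fry). Scaled by library totals, the medians of the oxidative phosphorylation and mitosis lists were -0.149 and -0.122. Ccnb1 and Ube2c had values of -0.50 and -0.52 (adjusted p = 0.00839 and 0.0121), and both missed the threshold without CML replicate 2 (0.0616 and 0.0517). DNA replication genes did not differ as a list (2 of 28 higher, 2 lower, the same adjusted over the list alone, camera adjusted p = 0.774), and Tyms rose by 0.50. Cytosolic ribosomal protein genes fell in 4 of 35 cases and rose in 0 (4 and 0 adjusted over the list alone; median -0.11, camera adjusted p = 0.0396; adjusted p = 0.883 with an estimated correlation), led by Rpl5 with -0.62. That list missed the threshold without CML replicate 2 (0.191), CML replicate 3 (0.0819) or WT replicate 3 (0.405), and with fry (0.369), library totals (0.0775) or a filter at a mean of 50 counts (0.0933). Its median ran from -0.209 without CML replicate 1 to -0.00188 without WT replicate 3, and CML replicate 1, at 0.04, lay among the WT libraries (-0.10, -0.07 and 0.20).

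Type I interferon response genes fell in 11 of 32 cases and rose in 1 (13 and 3 adjusted over the list alone; median -0.35, camera adjusted p = 7.39e-04; adjusted p = 0.537 with an estimated correlation and 0.0865 with fry). Per library the list's median was -0.29, -0.20 and -0.44 in CML replicates 1, 2 and 3, and WT replicate 1, at -0.23, lay within that range, with WT replicates 2 and 3 at 0.18 and 0.05. Rsad2, an antiviral enzyme gene, was at 13.6 ± 0.35 CPM in CML and 47.1 ± 11.8 CPM in WT (log2 fold change -1.79, SE 0.17). Cmpk2, its genomic neighbour, fell by 0.88, Ifi44 by 1.17 and Mx2 by 1.01.

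**Figure D4:**
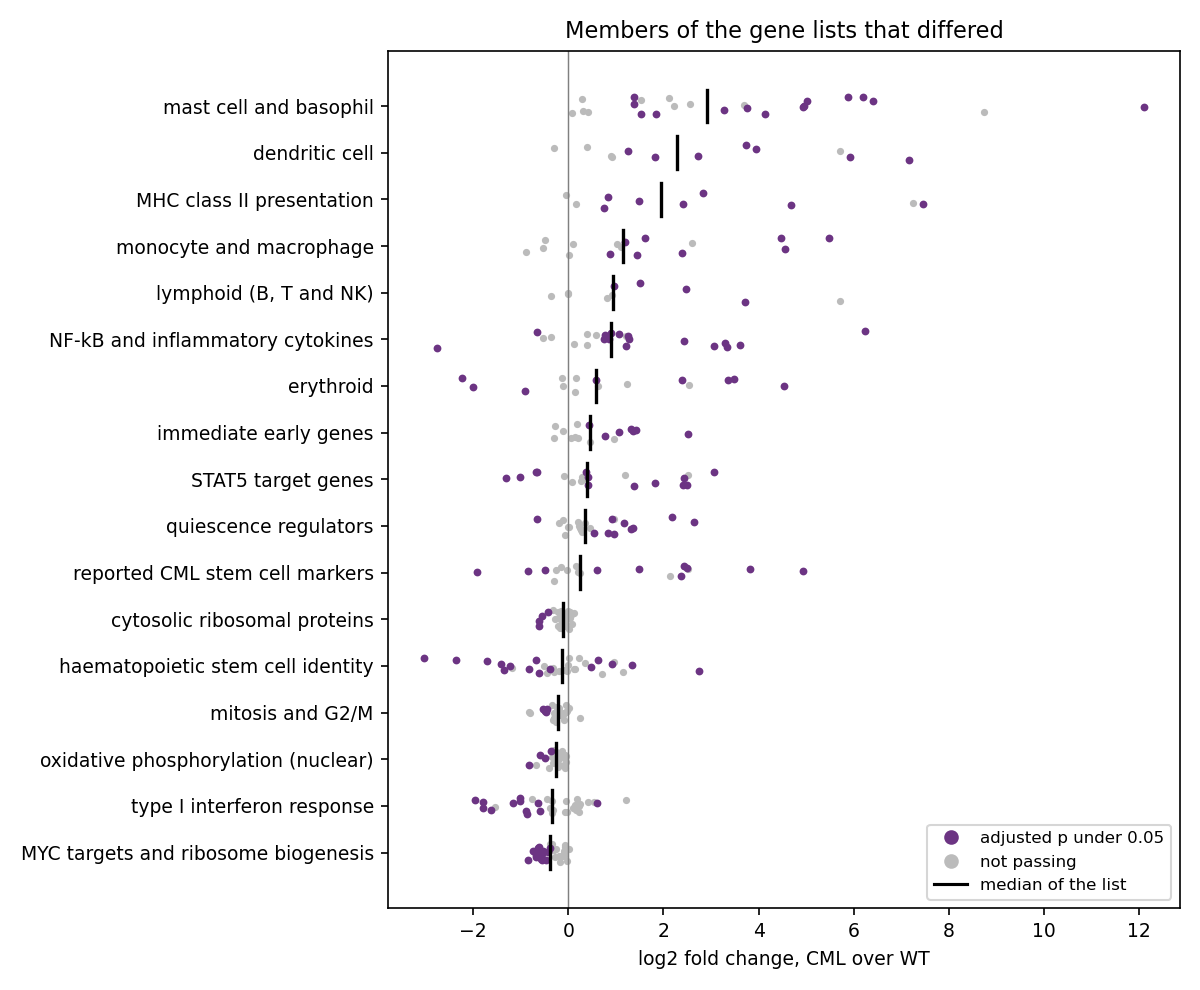
Log2 fold change, CML over WT (x axis), of each tested member of the 17 lists that differed at the preset correlation (y axis). Purple points passed an adjusted p of 0.05, grey points did not, and black lines are list medians, from 2.91 for mast cell and basophil genes to -0.39 for MYC targets.

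None of 8 measures of library size and composition could pass an adjusted p of 0.05, since 3 libraries against 3 allow no exact permutation p below 0.1. Total counts were lower in each CML library than in any WT library (exact permutation p = 0.1). The 4 mitochondria-like pseudogene models, which match mitochondrial genes at 97.6% to 100% identity, took 2.75 ± 0.44% of counts in CML and 4.34 ± 0.83% in WT (exact permutation p = 0.1, the smallest possible; adjusted p = 0.16 over 8 measures). Detected genes numbered 26207 ± 772 in CML and 25085 ± 368 in WT (exact p = 0.1), a difference of 1122 that fell to 490.7 when at least 10 counts were required. An annotated ribosomal RNA model on chromosome 17 (39846353 to 39848827) took 1.28% of the counts of CML replicate 3, or 198233 counts. It had 1772 and 516 counts in CML replicates 1 and 2, and 49, 128 and 68 in WT replicates 1, 2 and 3. Its share was thus higher in each CML library than in any WT library (exact permutation p = 0.1, adjusted p = 0.16). The 10 most abundant genes took 7.75 ± 0.27% of counts in CML and 8.54 ± 0.70% in WT (exact p = 0.2), and the 7SL and Xist shares had exact p = 0.7 and 0.8.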

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

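Among the alternatives, 3 were chosen after seeing the data: the newer quasi-likelihood setting, removal of 7 technical models and removal of GC and length trends. With a log2 fold change of at least 1 as a further threshold, 1180 genes changed, 958 higher and 222 lower, by construction fewer. Scaled by library totals alone, 732 genes were lower, by construction fewer, since without TMM factors the log2 fold changes of all genes move up together (median over genes 0.094). Leaving out each library in turn gave 1466 to 4122 changed genes, 1011 to 2021 higher and 455 to 2101 lower, with fewer samples in each fit. Of the genes called with all libraries, 1394 were also called without WT replicate 2 and 2532 without WT replicate 3. With an estimated correlation 0 lists passed. The labels do not say whether a replicate number marks a shared animal, day or batch. The deviation correlations across genes of same-numbered libraries were -0.02, -0.05 and 0.01, and no library correlated best with its own number. With 3 libraries per group these correlations cannot exclude a pairing. With the replicate block, 2807 genes changed, 1607 higher and 1200 lower, and 17 lists passed: the RAS-ERK list was gained (adjusted p = 0.0441) and the erythroid list was not called (0.105). Prg2 passed with the block (2.15, adjusted p = 0.00422) and Idh3a did not (0.0503). The GC and length trends gave Spearman coefficients of 0.30 and 0.07 with log2 fold change across genes, which are not independent replicates. After their removal 2999 genes changed, 2381 of them shared with the calls of the main test. Named genes kept direction and side of the threshold in 2291 gene-setting pairs, lost the call in 153, gained it in 2 and reversed in 3. The reversed values, none past the threshold, were 0.024 for Xist with GC and length trends removed, 0.040 for Bcr without CML replicate 1 and -0.160 for Kit without CML replicate 2; the cause was not tested. Leaving out each library gave -0.272 to 0.040 for Bcr and -0.160 to 0.303 for Kit. Lists kept their side in 497 pairs, lost the call in 33 and gained it in 13. At these depths, dispersions and library numbers, 20.9% of simulated changes by a factor of 1.5 were recovered, with far fewer changed genes than were called here. The simulation did not vary depth, and thinning to the smallest library gave 2774 changed genes.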

Other observations

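The tests that compare ratios between CML libraries and the test on stem cell genes were chosen or revised after their results were seen, and the second marker sets were written before their own values were seen. The expected share in the test of a single admixed source was reworded after that test had run, with its bound unchanged. Several lists that did not differ as a whole held members with clear changes. Among ABC and SLC drug transporters, 2 of 10 tested members rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.436, fry 0.0224). Abca1, a cholesterol exporter gene, rose by 2.85 on the log2 scale to 86.1 ± 17.9 CPM (SD, n = 3), and Abcg2, an exporter gene of stem cells, fell by 0.72, both past the edgeR threshold. Among apoptosis regulators of the BCL2 family 4 of 15 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.825). Bcl2 fell by 0.98 from 115 ± 8.91 CPM in WT and Bok by 2.57, while Bcl2l11, which encodes BIM, rose by 1.08 and Bcl2a1d by 2.56, a value that is uncertain because its paralogues are near identical. Among adhesion and homing genes 6 of 21 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.971). Itgb2 and Cd44 rose by 0.83 and 0.60, and Itga6 and S1pr1 fell by 0.72 and 1.70. Megakaryocyte genes rose in 3 of 22 cases and fell in 3 (4 and 3 adjusted over the list alone; camera adjusted p = 0.929). Itgb3 rose by 1.64 to 185 ± 35.04 CPM, Thbs1 by 3.05 and Rab27b by 0.82. In the stromal and endothelial list 1 of 5 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.503). Pdgfrb, a growth factor receptor gene, rose by 1.91 to 106 ± 9.97 CPM and Kdr fell by 1.77. None of the 3 tested eosinophil genes passed (0 adjusted over the list alone; camera adjusted p = 0.925), and Prg2 had a log2 fold change of 2.33 (SE 1.15, adjusted p = 0.249), or 1.01 without CML replicate 3.

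In p53 targets 5 of 23 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.185). Cdkn1a, the cell cycle inhibitor p21, rose by 0.95, Fas rose by 1.43 and Eda2r fell by 0.95. The ATF4 amino acid response held 0 higher and 4 lower of 21 (the same adjusted over the list alone; camera adjusted p = 0.468), and Slc7a11, the cystine transporter, fell by 0.91 and Psat1 by 0.56. Endoplasmic reticulum folding genes held 0 higher and 4 lower of 18 (1 and 4 adjusted over the list alone; camera adjusted p = 0.116), and the list passed without CML replicate 1 (adjusted p = 0.0445) and with no low-count filter (0.0112). Canx had a value of -0.60, which missed the threshold without CML replicate 3 or WT replicate 2 (adjusted p = 0.0560 for each). Glycolysis genes held 2 higher and 3 lower of 24 (the same adjusted over the list alone; camera adjusted p = 0.257), the list passed with GC and length trends removed (median -0.167, adjusted p = 0.0106), and Pgk1 fell by 0.57 and Pdk1 by 0.51. Cholesterol genes held 0 higher and 1 lower of 22 (the same adjusted over the list alone; camera adjusted p = 0.142); the list passed without CML replicate 2 (0.00264) and with no low-count filter (0.0166). Fatty acid genes held 2 higher and 2 lower of 20 (the same adjusted over the list alone; camera adjusted p = 0.756), and Srebf1 rose by 0.75. The list median and the camera direction differed in sign for the gate, megakaryocyte, ATF4, adhesion and ABC lists, and the mean and median did so for the eosinophil, stromal, ATF4, HOX and ABC lists.

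The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. The real split gave 2820 changed genes, 1652 higher and 1168 lower. The highest count of any other split was 0 for each, so 1 of the 10 splits gave as many. Every other split holds CML and WT libraries on both sides, so the group difference enlarges its residual spread. A count near 0 is therefore likely in advance there, and the comparison does not measure chance. For lists the real split gave 17, the other splits gave 5 to 24, and 4 of the 10 splits, the real one included, gave at least 17. The 3 other splits that reached this number, with 19, 20 and 24 lists, all set CML replicates 2 and 3 apart from CML replicate 1. Those 2 libraries lay farther from WT on the first principal component (-58.8 and -51.0) than CML replicate 1 (-35.2). Such splits therefore still carry part of the group difference, and a structure within the CML libraries cannot be told apart from it.

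Mast cell and basophil genes were higher in CML. A candidate explanation is that mast-type cells, which carry cKit, passed the sort or arose in culture, since the order of sort and expansion is not given. A second set of 17 mast cell genes, none of them in the fixed lists, gave 9 of 14 tested members higher and 0 lower, with a median log2 fold change of 1.30 (SD 2.28), past the 1 set beforehand, and with 0.59, 1.52 and 1.33 in CML replicates 1, 2 and 3; the 9 members with a mean of 5 CPM or more in WT had a median of 0.56, from -2.17 for Cnrip1 (adjusted p = 0.0559) to 2.21 for Hs6st2, with Alox5ap at 0.06 and Hpgds at 0.01 (all 4 chosen after their values were seen). Whether such cells carry all strongly raised genes was not decided by the bound set. Of 76 other genes at least 10-fold higher, 42.1% had a smaller ratio of CML replicate 2 to replicate 1 than each of 8 mast cell members. A common source would give about 1 in 9, and over 50% was set as the bound against it. The share lies near that bound without reaching it. Among the largest increases, Igfbp5, Trgc4, Mgl2, Eomes and Sprr2a2 lay below each of these members, and Tph1, Efna5, Akr1c18 and Anpep did not. The mast cell ratio was thus not common to all of these genes. Mast-type cells and a mast cell programme within the leukaemic cells, which is the group difference itself and was not tested, both stay open.

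MHC class II and dendritic cell genes were higher in CML, most in replicates 2 and 3. Whether they share a source with the mast cell genes cannot be told apart: the median log2 ratio of CML replicate 3 to replicate 2 was -0.70 for 14 called mast cell members (SD 0.54) and -0.06 for 14 called MHC class II and dendritic members (SD 0.53), a difference of 0.64, while that of replicate 2 to replicate 1 was 1.47 (SD 0.53) and 1.54 (SD 1.07). Dendritic-type cells may contribute, and a second set of 19 dendritic genes gave 9 of 14 tested members higher and 0 lower, with a median of 0.96 (SD 1.55), short of the 1 set beforehand, so they and a change within the CML cells cannot be told apart. The 7 members with a mean of 5 CPM or more in WT had a median of 0.48. A gate on cKit, Sca1 and CD150 excludes cells without these proteins, but cells that arose in culture after a sort need not have met it.

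Stem cell identity genes differed between CML and WT. A lower share of stem cells in the CML libraries could lower them, and cannot be told apart from a change of programme in the CML cells: of 32 tested members 10 were called lower and 5 higher, and not every member is specific to stem cells, so neither count decides.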
